A study of Mus musculus with 6 samples.

How the data were processed

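Cytosine methylation was measured by enhanced reduced representation bisulfite sequencing, in which DNA is cut with the restriction enzyme MspI, treated with bisulfite and sequenced, so that CpG-rich fragments are read at high depth. Bisulfite reads 5-methylcytosine and 5-hydroxymethylcytosine alike, and every methylation level below is the sum of both. The 6 libraries came from splenic germinal centre B cells of C57BL/6 mice, 3 labelled Tet2 WT and 3 labelled Tet2 KO. Per the submitters' processing notes the reads were aligned with Bismark to GRCm38. The Bismark version, the test and the thresholds the authors used are not given in the sources used here.

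Each deposited file lists CpG positions on each strand, with the coverage as a count of reads and the percent of reads called C and T, per the file headers. The lowest deposited coverage count was 10 in each library. Counts of methylated and unmethylated reads were recovered from the deposited coverage and percent values, and came out whole at all positions within the rounding of the percent values to 3 decimals. Reads of another base made up 0.0172% to 0.0189% of reads per library and were left out of the levels. PCR copies were not told apart from independent molecules, so intervals from read counts would cover counting error only. Nothing in the labels says how the replicates were obtained beyond their numbers, so p-values measure the spread between these libraries, which may be partly technical.

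Comparisons used the 1463044 CpG positions with at least 10 reads in all 6 libraries, out of 2029165 listed in any. CpGs were tested singly and after adding reads over 1 kb tiles with at least 3 CpGs, over gene ends with at least 3 CpGs and over gene bodies with at least 5 CpGs. Genes were the 21887 protein-coding genes of the RefSeq table for GRCm38.p6, which was used without strand, exons or sequence. The planned promoter was therefore replaced by the CpG-denser gene end, the 1 kb on either side of whichever annotated end held more covered CpGs. That end had a median methylation of 0.913% against 81.8% at the other end, over 3270 genes with both ends covered. Ends at so low a level fell outside the tested range given below, and 3708 of 14434 covered ends were tested. Those called had WT means of 9.73% to 59.5%, so this check cannot tell whether they are promoters. Exons, introns, CpG islands and repeats were not analysed here, and CpG density was described by the covered CpG positions within 250 bp, a choice made after the files had been seen.

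Each feature was tested with a quasi-binomial logistic model whose Pearson dispersion, on 4 degrees of freedom, was moderated across all features with limma's empirical Bayes method, written in Python and equal to limma's squeezeVar on test values. Features with a mean methylation of 5% to 95% were tested, p-values were adjusted by Benjamini-Hochberg, and a feature was called at an adjusted p under 0.05 with group means at least 10 percentage points apart. Group means are unweighted means of the 3 libraries. Mean levels were compared by exact two-sided permutation tests, for which 3 libraries against 3 give a smallest p of 0.1. The 17 gene lists were fixed before the data were examined and tested with camera in limma on log2 ratios of methylated to unmethylated reads, with an offset of 1 and a preset correlation of 0.01. All listed symbols matched the gene table except in the imprinted list (19 of 23) and the interferon list (20 of 22). Whether a list held more called tiles than other tiles within 5 kb of genes was tested with Fisher's exact test, added after the data had been seen. Neighbouring CpGs and tiles are not independent, so Fisher p-values are too small.

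The method was tested on simulated data with 200 changed features. In beta-binomial data for 83114 tiles it recovered 23.9% of changes of 15 points, 85.1% of 30 points and 100% of 50 points, and 10.9% of its calls were false. Among 525213 single CpGs it recovered 0% of changes of 15 or 30 points and 37.9% of 50 points, with 0 false calls. A simulation of repeatedly read molecules, added after that result, recovered 0% at all 3 sizes for single CpGs and 23.9%, 79.1% and 100% for tiles, with 8.78% of tile calls false. The simulated beta-binomial data had other prior degrees of freedom than the real data, 14.3 against 87.4 for CpGs and 30.9 against 9.35 for tiles, so these shares do not carry over to the real tests.

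Genes were named by a rule fixed beforehand. It took the 12 called tiles with the largest rise and the 6 with the largest fall whose groups did not overlap, then the 10 gene ends and 6 gene bodies that rose most and the 5 and 3 that fell most. It added up to 4 called members of each list, or at most 2 with the smallest p where none was called, and a fixed set of genes of methylation and germinal centre biology whatever their test. Without strand, flanks and distances refer to either annotated end. Some genes that this rule selects are not reported here. Predicted genes and immunoglobulin or T-cell receptor segments were counted but not named. Alternatives changed the coverage minimum, strand handling, the dispersion model, the test, the thresholds, tile size, the chromosomes used, the replicate block and each library in turn. A promoter of unequal upstream and downstream lengths was not run because strand was not used here. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.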

Results

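DNA methylation was profiled in splenic germinal centre B cells, the dividing B cells that diversify their antibodies during an immune response, from mice with and without Tet2, an enzyme that oxidises 5-methylcytosine. The 3 Tet2 WT libraries held 178955262, 174375503 and 203863392 reads over CpGs in replicates 1, 2 and 3, and the 3 Tet2 KO libraries held 195582108, 183417223 and 180397494. Mean coverage per listed CpG was 101 to 125 reads. Methylated calls on mitochondrial DNA were 0.241% to 0.410% of reads.

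The Tet2 locus was examined first as a check of the labels. Tet2 lies on chromosome 3 from 133463677 to 133545136 (GRCm38). Within it, 6 CpG positions from 133486189 to 133486297 were listed in each Tet2 WT library, with 32 to 168 reads, and in no Tet2 KO library. Another 108 Tet2 CpG positions were covered in all 6 libraries, at a mean of 92.4 to 125 reads. Tet2 gene-body methylation was 89.8% ± 2.06 in WT and 93.8% ± 1.41 in KO (SD, n = 3 each; adjusted p = 0.270, limma-moderated quasi-binomial test), which did not pass.

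The first comparison asked whether methylation differed across the genome without Tet2. Gene bodies averaged 49.4% ± 0.694 in WT and 50.7% ± 0.179 in KO (SD, n = 3 each), a difference of 1.29 points. CpGs between 20% and 80% were at 54.99% ± 1.82 in WT and 59.1% ± 0.333 in KO; this class was cut on the mean of all 6 libraries, which draws CpGs with large differences into it. CpG-denser gene ends were low in both groups, at 4.08% ± 0.0834 and 4.28% ± 0.0449. Over all covered CpGs the means were 33.0% ± 0.413 and 33.8% ± 0.150, a difference of 0.770 points. In each of these classes the lowest KO library lay above the highest WT library, which gives an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow, and an adjusted p of 0.115 over 15 contexts. On the X chromosome and in CpGs over 80% methylated the groups overlapped (exact permutation p = 0.2 each), with differences of 0.293 and 0.746 points, the latter 0.0492 without WT replicate 1. Over all covered CpGs the WT libraries correlated less with each other (mean Pearson r = 0.9698) than with KO libraries (0.9746), and KO libraries most with each other (0.983). The first principal component (28.7% of variance) set WT replicate 2 apart, and none of the first 3 separated the groups. Methylated reads over all reads gave a difference of 1.26 points, with overlapping groups (exact permutation p = 0.5).

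**Figure D1:**
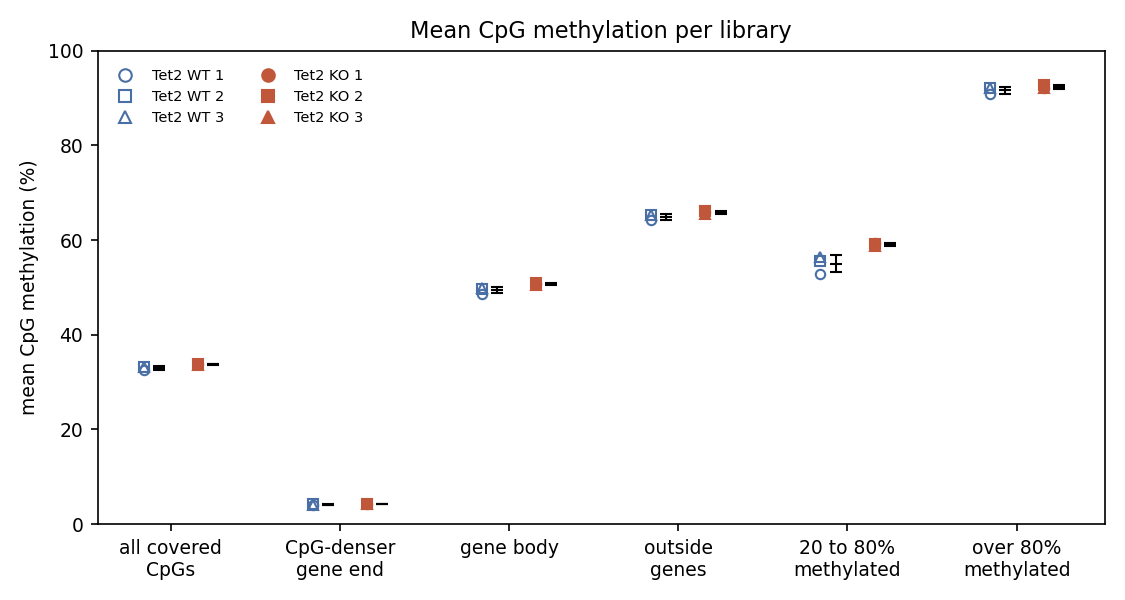
Mean CpG methylation in percent (vertical axis) of each of the 3 Tet2 WT (open) and 3 Tet2 KO (filled) libraries by CpG class, with group means and SD as black bars. CpGs of intermediate methylation averaged 54.99% in WT and 59.1% in KO, and CpG-denser gene ends 4.08% and 4.28%.

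The second comparison asked which regions differed. Among 1 kb tiles with the largest rises, that in Mtmr3, a phosphoinositide phosphatase gene, was 33.1% ± 10.99 methylated in WT and 81.2% ± 4.09 in KO (SD, n = 3 each; chromosome 11, 4534001 to 4535000, adjusted p = 0.00223). The tile in Ptprj, a receptor tyrosine phosphatase gene, was at 15.8% ± 7.13 and 61.3% ± 0.679 (chromosome 2, 90478001 to 90479000, adjusted p = 0.00342). Tiles in Nek7, Grhpr, Cmtm7, Sox5 and Tbc1d17 rose by 45.2, 45.4, 45.7, 44.5 and 43.4 points. The remaining large rises lay outside genes, nearest to Ado, Dph5, Lmo4, Auh and Cass4, at 74046, 30116, 27746, 42107 and 2644 bp, and measured 53.0, 50.3, 49.9, 46.0 and 42.5 points. These 12 tiles held 3 to 9 CpGs, and their reads summed over CpGs were 55 to 1126 per library. The 2 tiles that fell were in Pik3c3, a lipid kinase gene of autophagy, from 66.9% ± 7.29 to 40.1% ± 9.34, and in Unc79, from 99.2% ± 0.883 to 88.5% ± 2.82. Of the 12 rises, 10, 11 and 12 were still called without WT replicates 1, 2 and 3, and 8, 8 and 7 without KO replicates 1, 2 and 3 (highest adjusted p = 0.263). Neither fall was called without WT replicate 1 or any KO replicate, and 1 of the 2 was without WT replicate 2 or 3 (highest adjusted p = 0.166).

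**Figure D2:**
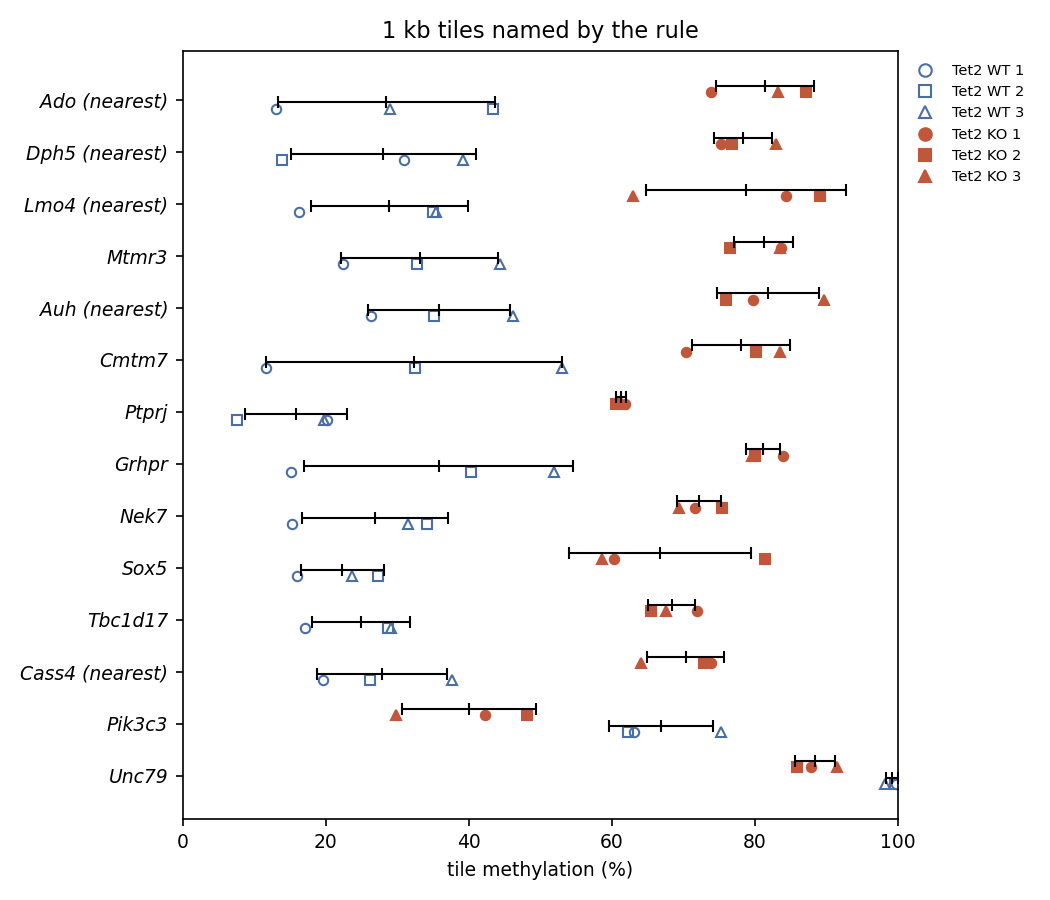
Methylation in percent (horizontal axis) of the 1 kb tiles named by the rule in each Tet2 WT (open) and Tet2 KO (filled) library, with group means and SD as black bars. The 12 upper tiles were higher in KO, the Ado tile by 53.0 points, and the Pik3c3 and Unc79 tiles were lower.

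Across the genome, 569 tiles were higher and 2 lower in KO among 83114 tested. The rises had a median of 21.0 points, from a median WT level of 44.7% to a median KO level of 72.0%. Of the higher tiles 412 (72.4%) lay in or within 1 kb of a protein-coding gene, against 58.1% of tested tiles (odds ratio 1.90, Fisher's exact test, p = 1.88e-12). Ebf1, which encodes a transcription factor that establishes B-cell identity, held 3 higher tiles, and 33 genes held at least 2, among them Pole2, Zfp362, Runx3, Ccr7, Nfkbie and Irf4. The groups did not overlap in 567 of the 569 higher tiles, which their selection on these same libraries largely fixed. Over all tested tiles the groups did not overlap in 16.2%, where chance gives 10%. Limma on log2 ratios and the same model with unmoderated dispersion called 0 tiles, with 7810 and 7173 at an unadjusted p under 0.05, and a test of all covered tiles called 8. Leaving out WT replicate 1 or 3 gave 209 and 1181 tiles, and leaving out KO replicate 1, 2 or 3 gave 143, 119 and 137.

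At single CpGs, gene bodies held more of the rises than of the positions tested, and CpG-dense positions held fewer. The contexts were not matched on methylation level, so effects of level and of context were not told apart. Tested CpGs under 20% or over 80%, by the mean of all 6 libraries, were called higher less often (odds ratios 0.412 and 0.0717). Gene bodies held 873 (58.6%) of the higher CpGs and 48.0% of those tested (odds ratio 1.54, adjusted p = 7.05e-16, Fisher's exact test), and the less CpG-dense gene ends held 56 (odds ratio 1.59, adjusted p = 0.00145). CpG-denser gene ends held 89 (odds ratio 0.484, adjusted p = 4.67e-13), and positions with 25 or more covered CpGs within 250 bp held 29 (odds ratio 0.174). Those dense positions held 15 of the 55 lower CpGs (odds ratio 3.29, adjusted p = 0.00405). Of the 55, 11 lay at the ribosomal DNA on chromosome 17, at a mean coverage at least 7.91 times the library mean. How many of these 11 were dense positions was not counted, so a single repeat locus may carry that enrichment. The X chromosome held 8 higher CpGs (odds ratio 0.268) and the Y chromosome 20 of 785 tested (odds ratio 9.31). In all, 1489 positions were higher and 55 lower in KO among 525213 tested. Limma, the unmoderated model and a test of all covered CpGs called 0. They gave an unadjusted p under 0.05 at 34083 of 525213, 34364 of 525213 and 81675 of 1463044 CpGs. With the moderated test, such a p was found at 8.70% of tested CpGs. In beta-binomial and repeated-molecule simulations with nothing changed, it was found at 5.95% and 6.74%. Leaving out WT replicates 1, 2 and 3 gave 666, 3135 and 3630 CpGs, and leaving out KO replicates 1, 2 and 3 gave 397, 220 and 745.

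Few whole gene ends or gene bodies passed. At CpG-denser gene ends, H2-Oa, which encodes a chain of a regulator of antigen loading, rose from 36.5% ± 2.12 to 59.2% ± 2.78 (SD, n = 3 each; chromosome 17, 34094234 to 34096234, adjusted p = 0.00638). The end shared by Tbc1d17 and Il4i1, an amino acid oxidase gene, rose from 9.73% ± 1.91 to 27.9% ± 3.24, and that of Lexm from 59.5% ± 3.998 to 75.5% ± 1.55. With a predicted gene, 5 of 3708 gene ends were higher and 0 lower, where 470 had an unadjusted p under 0.05. The end shared by Tbc1d17 and Il4i1 counts once for each gene, here and in the counts that follow. Limma and the unmoderated model called 0 ends, with 434 and 351 at an unadjusted p under 0.05. A test of all 14434 covered ends also called 0, with 1192 at such a p. Of the 4 named ends 0, 3 and 3 were still called without WT replicates 1, 2 and 3, and 1, 1 and 3 without KO replicates 1, 2 and 3 (highest adjusted p = 0.180). In all, 0 ends were called without WT replicate 1, 12 without WT replicate 3, and 1, 2 and 3 without KO replicates 1, 2 and 3.

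The gene body of Pole2, a DNA polymerase epsilon subunit gene, rose from 54.0% ± 8.83 to 84.0% ± 0.708, and that of the zinc finger gene Zfp362 from 13.6% ± 3.12 to 40.03% ± 1.78 (SD, n = 3 each; adjusted p = 0.0275 and 0.0105). Gene bodies of Cytip, Adat3, Coro2a and Scamp4 rose by 15.5, 13.0, 12.1 and 11.8 points, where Adat3 and Scamp4 overlap. With CpGs weighted equally, Cytip and Coro2a differed by 9.06 and 6.05 points, under the threshold of 10. In all, 6 of 10562 gene bodies were higher and 1 lower. Limma and the unmoderated model called 0, with 1717 and 1460 at an unadjusted p under 0.05. Of the 6 rises 1 was still called without WT replicate 1, 2 without WT replicate 2, 6 without WT replicate 3 and 0 without any KO replicate (highest adjusted p = 0.305). In all, 2, 2 and 109 gene bodies were called without WT replicates 1, 2 and 3, and 0 without each KO replicate.

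The gene body called lower was that of Vav1, which encodes a signalling protein of blood cells, at 54.5% ± 3.39 in WT and 32.3% ± 1.18 in KO (SD, n = 3 each; adjusted p = 0.0105). With its 33 CpGs weighted equally, Vav1 was at 70.4% ± 1.84 and 73.8% ± 1.23, a difference of 3.48 points in the other direction. Coverage of 7 unmethylated Vav1 CpGs on chromosome 17 from 57290473 to 57290718, chosen after their values were seen, was 3.23 times as high in KO as in WT relative to each library's mean, against 1.05 times for the other 26. The call was lost without WT replicate 2 (adjusted p = 0.0535) and without KO replicates 1, 2 and 3 (adjusted p = 0.0945, 0.0682 and 0.0915), while Vav1 differed by -22.5, -21.7, -22.8 and -22.1 points. With CpGs of the highest coverage left out Vav1 differed by -2.01 points (adjusted p = 0.734, limma-moderated test).

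**Figure D3:**
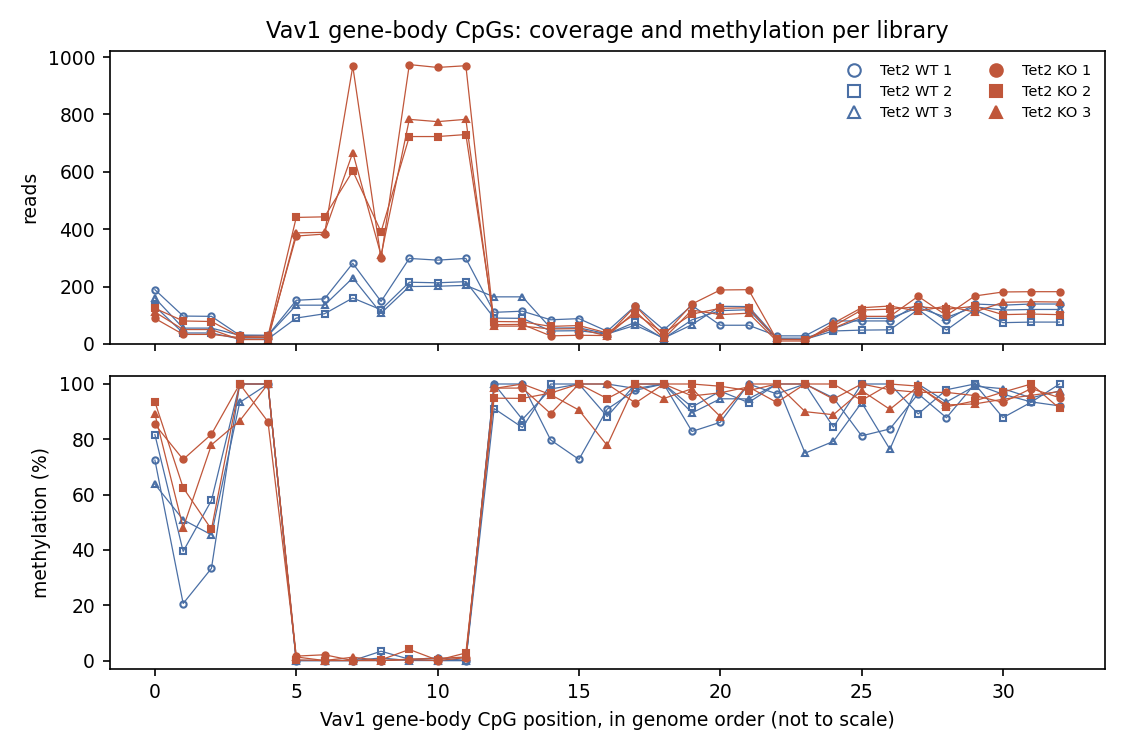
Reads (upper panel) and methylation in percent (lower panel) at the 33 covered Vav1 gene-body CpGs in genome order, for each Tet2 WT (open) and Tet2 KO (filled) library. The 7 unmethylated CpGs had 3.23 times the relative coverage in KO.

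Tiles of several B-cell gene lists were called higher more often than gene tiles in general. Naive and follicular B-cell genes held 5 higher tiles among 37 (adjusted p = 0.000228, Fisher's exact test), 10 when adjusted over the list alone. They lay at Ccr7 and Cxcr5, chemokine receptor genes that place B cells in lymphoid tissue, Gpr183, a receptor gene for follicle positioning, and Cd37, a tetraspanin gene. The Cd37 tile was at 38.1% ± 6.63 in WT and 73.3% ± 2.71 in KO, and the Ccr7 tile at 35.0% ± 23.5 and 76.2% ± 2.25 (SD, n = 3 each). Plasma-cell genes held 4 of 56 (adjusted p = 0.00787; 6 adjusted over the list alone), at Slamf7, Zbtb20 and Irf4, a transcription factor gene of plasma-cell formation, whose tile rose by 19.2 points. The germinal centre programme held 6 of 145 (adjusted p = 0.00787; 13 adjusted over the list alone), at Ebf1, Pax5, Myo1e and Irf8, with rises of 24.1, 20.1, 19.5 and 12.3 points. B-cell receptor, CD40 and NF-kB genes held 5 of 131 (adjusted p = 0.0207; 7 adjusted over the list alone), among them tiles at Nfkbie, Ptpn6 and Blnk, with rises of 27.3, 26.2 and 23.1 points, and include Vav1. These were 4 of 17 lists, set against 433 higher tiles (0.829%) among the 52202 tested within 5 kb of any gene. Rises, whether called or not, were as common in some other lists. KO means were above WT means in 80.9% to 89.2% of tiles in these 4 lists. They were so in 92.1% of antigen presentation, 90.6% of cell cycle and 92.9% of natural killer tiles. The remaining lists ran from 60.9% to 82.9%, against 64.0% of all tested tiles. Without WT replicate 1 the lists that passed were the naive and follicular list and T-cell genes (2 lists), without KO replicate 1 the naive and follicular list alone (1 list), without KO replicate 2 or 3 there were 0, and testing all covered tiles gave 0. The B-cell receptor list was also lost without WT replicate 2 (adjusted p = 0.105), on autosomes only (0.0953), with coverage in 2 libraries per group (0.0809) and without a chromosome 1 segment (0.0994), with odds ratios of 3.13, 3.88, 4.08 and 3.82 against 4.79, and the plasma-cell list with a replicate block (0.0997), by Fisher's exact test.

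Single named tiles of these lists also depended on the libraries. Without WT replicate 1, 2 of 4 naive and follicular, 2 of 3 plasma-cell, 0 of 4 germinal centre and 1 of 4 B-cell receptor tiles, 1 of them not named above, were still called, and without WT replicate 2, 3, 2, 3 and 3 of them. Without KO replicate 1 the numbers were 2, 0, 0 and 1, without KO replicate 2 each was 0, and without KO replicate 3 they were 1, 0, 0 and 0. The highest adjusted p was 0.165, 0.194, 0.204 and 0.246 in these lists.

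The camera test on gene bodies called the naive and follicular list alone, upward (12 genes, adjusted p = 0.0230, limma), with adjusted p = 0.873 with an estimated correlation. Its median change was 0.52 on the log2 scale, against 0.19 over all gene bodies. No list passed without WT replicate 1 or 3 or KO replicate 1. On gene ends camera in limma called 0 of the 17 lists, with 2 at an unadjusted p under 0.05, antigen presentation and erythroid genes (adjusted p = 0.401 each).

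Single members of other lists also held higher tiles, in lists that did not pass the enrichment test and had odds ratios of 1.31 to 3.24. These were H2-Oa in antigen presentation (1 of 38 tiles; 7 adjusted over the list alone), Dnmt3a and Ung in the methylation machinery (2 of 76; 6 adjusted over the list alone) and Ccnd3 in the cell cycle (1 of 64; 7 adjusted over the list alone). Among markers of other cell types, Runx3 and Zap70 of T cells (3 of 141; 4 adjusted over the list alone), Itgam of myeloid cells (1 of 41; 2 adjusted over the list alone) and Pecam1 of endothelium (1 of 92; 2 adjusted over the list alone) held higher tiles. The Runx3 tile, in a gene also used by B cells, was at 50.6% ± 11.6 in WT and 80.3% ± 2.29 in KO (SD, n = 3 each). The H2-Oa tile was called whichever library was left out (highest adjusted p = 0.0327), and the T-cell tiles without any WT replicate, with 1 of 2 left without each KO replicate. The Ccnd3 and Itgam tiles were lost without WT replicate 1 or any KO replicate, Itgam also without WT replicate 2, Pecam1 without KO replicate 1 or 2, both Dnmt3a and Ung without WT replicate 1 or KO replicate 1 or 3, and 1 of these 2 without WT replicate 3 or KO replicate 2 (highest adjusted p = 0.154, 0.165, 0.1002 and 0.169).

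No tile was called by the moderated test at 409 tiles of Polycomb-bound developmental regulators, 73 of lymphoma genes, 74 of imprinted genes, 34 of interferon genes, 101 of stem and progenitor genes, 59 of erythroid genes and 14 of natural killer genes. Adjusted over the list alone, 1 lymphoma tile and 1 natural killer tile passed and 0 in the other 5 lists. Higher tiles were called without WT replicate 3 in Polycomb-bound, imprinted, stem and progenitor and natural killer genes (odds ratios 0.142, 0.794, 0.566 and 4.58), and with a replicate block in imprinted, interferon and stem and progenitor genes (odds ratios 1.06, 2.34 and 0.770), and none of the 7 lists passed in either case (lowest adjusted p = 0.0516, Polycomb-bound genes, Fisher's exact test). With no overdispersion each of the 7 lists held higher tiles, and Polycomb-bound genes held fewer than other gene tiles (odds ratio 0.164, adjusted p = 6.74e-07). The smallest p-values were at Arid1a (87.3% ± 1.66 in WT and 93.5% ± 0.922 in KO) and Gna13 for lymphoma genes, Hoxa3 and Hoxa5, which share a tile (21.8% ± 1.66 and 27.1% ± 0.733), Igf2r and Gnas, Irf1 for interferon genes, Hlf and Runx1, Epor and Rhd, and Il2rb and Tbx21 (SD, n = 3 each).

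Other genes of methylation and of the germinal centre were given whatever their test. Gene-body methylation of Dnmt1, the maintenance methyltransferase gene, was 41.8% ± 0.654 in WT and 44.9% ± 0.447 in KO, and that of Dnmt3a 13.1% ± 0.0783 and 15.6% ± 0.926 (SD, n = 3 each). Tet1, Tet3, Dnmt3b and Uhrf1 gene bodies differed by 1.85, 2.71, 0.6502 and 3.77 points. Those of Bcl6, Prdm1, Irf4 and Bach2 differed by -2.03, 3.10, -1.37 and 2.68 points. None of these gene bodies passed, the lowest adjusted p being 0.0877 for Dnmt3a (limma-moderated test).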

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

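The tests of this part were set before their results were seen, except the comparison with other groupings of the libraries and the recount without the segment, which were chosen afterwards. Positions listed in the libraries of one group alone were outside the comparisons. The lowest listed coverage was 10 reads, so an unlisted position may still have had fewer reads than that. A set of 254 CpG positions had 30 or more reads in each Tet2 KO library and was listed in no Tet2 WT library. Of these, 246 lay on chromosome 1 between 80586933 and 105881834, while among the other groupings of 3 libraries the highest number was 128 positions, of which 1 lay in that segment. In the reverse direction, 22 positions had 30 or more reads in each WT library and were listed in no KO library, and 0 of them lay in that segment. A deletion in the WT libraries would lower coverage there, and the WT to KO ratio of relative coverage over 11039 shared CpGs was 1.004, which argues against it. A segment of another mouse haplotype in the WT libraries, with variants that remove MspI sites or CpGs, may account for the cluster, but its test could not decide, because 0 CpGs in the segment and 0 on other autosomes read under 20% in each WT and over 80% in each KO library. Without the segment, 561 tiles were higher and 2 lower in KO, and the lists with more called tiles went from 4 to 3, the B-cell receptor list being lost (adjusted p = 0.0994 against 0.0207, odds ratio 3.82 against 4.79, Fisher's exact test).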

How the results depend on the processing

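Alternatives were listed before the data were examined, except leaving out the chromosome 1 segment, testing both gene ends, weighting CpGs equally, and all recounts of list tiles and of the odds ratios by context, which were chosen after seeing the data. The mean difference over all CpGs, and those of the 4 contexts recomputed, kept their direction in each alternative run. The numbers of calls did not hold, and the cause was not tested unless stated. With no overdispersion, 108327 CpGs (69.6% higher), 5850 tiles (88.2% higher), 190 gene ends and 384 gene bodies were called. With unmoderated dispersion, with limma and with limma after centring, 0 CpGs, 0 tiles, 0 gene ends and 0 gene bodies were called, so no share could be given; after centring, 33321 CpGs, 6966 tiles, 348 gene ends and 1072 gene bodies had an unadjusted p under 0.05. An adjusted p under 0.01 and 25 points left 474 CpGs (99.8% higher), 62 tiles (100% higher), 0 gene ends and 0 gene bodies, from stricter thresholds. Testing all covered features left 0 CpGs, 8 tiles (100% higher), 0 gene ends and 0 lists with more called tiles. On autosomes only, with coverage in 2 libraries per group and without the chromosome 1 segment, 3 lists kept more called tiles, and the B-cell receptor list was lost (adjusted p = 0.0953, 0.0809 and 0.0994, odds ratios 3.88, 4.08 and 3.82 against 4.79, Fisher's exact test). With no overdispersion 6 lists passed, antigen presentation and cell cycle genes among them (adjusted p = 0.000718 and 0.00119). Requiring 20 reads gave 9 gene ends, testing both gene ends gave 8, and leaving out the highest coverage gave 4 gene bodies. Tiles with 5 or more CpGs gave 345 calls (100% higher), from fewer tiles tested. The share of higher CpGs was 97.5% with coverage in 2 libraries per group and 97.6% with strands added. Weighting CpGs equally kept the direction of 571 of 571 tiles, 546 of them at 10 points or more, and of 6 of 7 gene bodies, 4 of them at 10 points or more, and turned Vav1 to 3.48 points.

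Leaving out each library gave 220 to 3630 CpGs (88.0% to 100% higher), 119 to 1181 tiles (98.8% to 100% higher), 0 to 12 gene ends, 0 to 109 gene bodies, 0 to 4 lists with more called tiles and 0 to 1 list by camera on gene bodies. An estimated correlation left 0 lists by camera. Same-numbered libraries showed no shared deviation in CpG methylation (correlations 0.00718, -0.00290 and -0.000953). Methylated mitochondrial reads were 0.260% and 0.258% in WT and KO replicate 1, and 0.410% and 0.408% in replicate 2. They were 0.241% and 0.294% in replicate 3, so whether the numbers pair libraries stays open. With a replicate block 0 CpGs, 892 tiles, 0 gene ends, 4 gene bodies and 0 lists by camera in limma were called, with 48171 CpGs and 461 gene ends at an unadjusted p under 0.05. The lists with more called tiles were then 3, the plasma-cell list being lost (odds ratio 4.38 against 9.27, adjusted p = 0.0997, Fisher's exact test). The mean difference was then 0.770 points (exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow). Over 48 named features, 814 values were recomputed, of which 500 held, 45 of these by direction and 10 points alone since equal weights were not tested, 313 kept their direction without the call and 1 reversed. A promoter with unequal upstream and downstream lengths was not run.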

Other observations

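The tests of Tet2 linkage, of ribosomal coverage, of equally weighted Vav1 CpGs and of unmethylated Vav1 coverage were chosen after the results had been seen. Calls were nearly all higher in KO. Incomplete conversion would raise unmethylated CpGs most, but CpGs under 5% rose by 0.131 points against 0.770 over all CpGs, and variants beside the targeted allele are argued against by the 0.712% of called CpGs within 10 Mb of Tet2. Unequal spread of the groups stays open: 10 simulations without a difference gave at most 0 called CpGs, but the bound set for that test was wrong, since the same model with equal spread recovered 0% of CpG changes of 30 points and 37.9% of 50 points, while the real rises had a median of 33.6 points. The 569 higher against 2 lower tiles argue against spread that is independent between tiles, but not against shifts that the tiles of a library share, as the exact permutation p of the mean difference was 0.1. Loss of Tet2 as the cause of the rise was not tested and stays open.

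The Vav1 gene body was called lower, but its CpGs weighted equally differed by 3.48 points upward, and the 16 CpGs with a KO to WT coverage ratio under 1.2 had a median difference of 2.33 points, which argues against a loss of methylation over the gene. A coverage test set for CpGs that fell by 10 points or more had 0 CpGs to run on. Coverage of the unmethylated stretch was 3.23 times as high in KO, and extra copies of Vav1 sequence, as in a transgene with Vav1 regulatory sequence, are a candidate explanation. The labels name no such transgene. CpG positions 57276851 and 57276876 on chromosome 17 lay just below the annotated Vav1 start at 57279100. They were among the 254 positions, described above, that were listed in each KO library and in no WT library. In WT they may still have had some reads, since the lowest listed coverage was 10. Whether they belong to extra copies was not tested.

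With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 1544 CpGs against at most 122, 571 tiles against at most 2, 5 gene ends against at most 1 and 7 gene bodies against at most 0 in the others.

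The mean SD within a group over tested CpGs was 9.74 points in WT and 7.05 in KO. The covariance shared by both strands of a CpG was 2.33 times as large in WT, and the WT to KO ratio of effective molecules per CpG strand was 0.960. The estimated number of effective molecules per strand ranged from 1.80 in WT replicate 2 to 2.12 in KO replicate 1, over 21836 CpG pairs. It was far below the mean coverage of 101 to 125 reads per listed CpG. The estimate came from the disagreement of both strands of a CpG within a library. A strand difference that recurs in every library lowers it, so it is not a count of molecules. For the same reason the ratio of 0.960 cannot decide whether the WT libraries held fewer molecules. Whether this estimate holds at the called CpGs was not tested. At the ribosomal DNA on chromosome 17 lay 11 of the 55 lower CpGs, whose mean coverage was at least 7.91 times the library mean in each library.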
